A study of Mus musculus with 8 samples.

How the data were processed

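RNA sequencing (RNA-seq) and whole-genome bisulfite sequencing (WGBS, which reads unmethylated cytosines as thymines) were run on CD4+ T lymphocytes of C57BL/6 mice, wild type (WT) or lacking Uhrf1 (Uhrf1 KO). Per the labels, naive CD4+ cells from lymph nodes were cultured with anti-CD3 and anti-CD28 at 1 µg/mL each, 50 µM mercaptoethanol and 10% serum. The labels give 3 days of culture and mice of 7 weeks for RNA-seq, and 60 h and 8 weeks for WGBS. Polyadenylated RNA was taken from 1 µg of total RNA, with a kit that does not mark the strand. Bisulfite libraries started from 5.2 µg of DNA with 26 ng of lambda DNA added.

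The labels list 3 RNA-seq samples per genotype and 1 WGBS sample per genotype. The count table holds 1 column of counts per genotype, and whether that column is 1 of the 3 samples or a merge of them is not given in the sources used here. Its group FPKM columns equalled the single FPKM columns in all 53951 lines. Each genotype was therefore treated as 1 library in each assay, and the edgeR quasi-likelihood tests, SDs and paired fits planned for RNA-seq were not run. No p-value across genes was computed. Another 2 per-sample columns of the count table, of normalized counts, were not used here.

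The deposited counts are whole numbers of reads per gene, and HISAT2 2.0.4, HTSeq 0.9.1 and edgeR are named for the RNA data per the submitters' processing notes. The authors also deposited FPKM values, used here only to compare the columns. Their table further gives a log2 fold change and p-values of KO against WT by the authors, from a comparison without replicates as far as the table shows. The table has 53465 Ensembl genes and 486 unannotated loci assembled by the authors. Of the Ensembl genes, 53274 were matched to a symbol by identifier. For 6 genes a line of the table was broken by a long annotation cell, and their counts were read from its first part. Reads of a gene and of an overlapping or antisense gene cannot be told apart in these counts.

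For WGBS, FastQC 0.11.5, Trimmomatic 0.36 and Bismark 0.16.3 are named per the submitters' processing notes. The deposited lists give methylated and unmethylated read counts per cytosine, its level as a fraction, and a p-value by the authors for being methylated. The lists hold cytosines called methylated and no others. The lowest coverage was 5 reads, the lowest level 5.0%, and the highest adjusted p-value by the authors 0.00959 in WT and 0.00991 in KO. At least 2 methylated reads stood behind each listed cytosine, and at least 3 behind each CHH cytosine in WT (H is A, C or T). A level over listed cytosines therefore overstates the true level in both libraries. With the same level at every cytosine, it does so more in the less methylated library. Data were simulated with the coverage of KO-listed CG cytosines and the same level at every cytosine. A true level of 30.0% came out as 33.7% at listed cytosines, with 79.3% of the cytosines listed, and one of 90.0% came out as 90.0%. Unmethylated cytosines and levels that vary between cytosines were not simulated, so the overstatement may be larger in both lists. The simulated 90.0% does not show that WT levels are free of it, since unmethylated cytosines are unlisted in WT too. A lower figure for KO was obtained by counting each cytosine listed in WT and missing from the KO list as 0%, although some of these may have had too few reads. The WT level was not lowered in a like way, so this figure widens the difference from WT and does not bound it. The authors' deposited table of differentially methylated regions (DMRs) gives a mean fraction per library, the difference of the means, the number of cytosines and a summed test score per region, and its caller is not given in the sources used here.

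The genome build is not named in the sources used here. Gene positions in the count table overlapped the GRCm38 positions of the same gene for 37559 of 37602 genes (99.9%), and positions are printed as the authors' files give them. No genome sequence or exon model was used. Exons, introns, untranslated regions (UTRs), CpG islands and repeats were therefore taken from the annotation inside the DMR table, whose repeat names include element families of primates. A promoter was the window from 1000 bp upstream to 500 bp downstream of the gene start. The Foxp3 promoter and its intronic conserved noncoding sequences (CNS1, CNS2, CNS3) were placed by approximate offsets from the Foxp3 start, without a check against sequence.

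RNA counts were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3 to normalised counts (CPM). Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. Genes were called expressed by the edgeR filter on low counts. A gene was called higher or lower when the libraries were at least 2-fold apart and the higher had at least 5 CPM. Genes counted as neither include those at least 2-fold apart but under 5 CPM, and their log2 ratios still enter the list medians. Each ratio of KO over WT carries an exact Clopper-Pearson 95% interval for counting error. Where a library had 0 counts, the ratio was bounded by setting it at 3 counts. Log2 ratios set any count under 3 at 3. On simulated counts for the 53951 lines with 200 genes altered, 4-fold, 2-fold, 0.5-fold and 0.25-fold ratios had medians of 4.02, 2.00, 0.503 and 0.248. Their 95% intervals held the simulated ratio in 96.0%, 94.0%, 98.0% and 96.0% of 50 genes each, and 0 of 10255 unaltered genes were 2-fold apart. Both simulated libraries were drawn from a shared profile with counting error alone, without variation between animals or cultures. The simulation therefore checks the computation and gives no rate of false calls for the real libraries.

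A set of 25 gene lists (T cell states, methylation, cell cycle, stress, germline, imprinted and other cell types) was compared with 10000 random lists of equal size matched on mean CPM, as a description of these libraries. Of 200 random lists of simulated values put through this step, 5.50% fell outside the 2.5 to 97.5 percentile range. Methylation levels are methylated reads over all reads at listed cytosines, with Wilson 95% intervals for the level of a region or library. Promoters entered with at least 5 listed CG cytosines in each library, and a difference of 20 percentage points was called. Reads at Foxp3 elements were compared by Fisher's exact test, two-sided, which compares 2 libraries and not the genotypes, with Benjamini-Hochberg adjustment over the 3 elements that had listed sites. All intervals cover counting error only, since reads without molecular identifiers are not independent molecules. A read that crosses several listed cytosines is counted at each of them. Intervals of regions and the Fisher's exact test take such counts as independent, which they are not.

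The lists, groups, thresholds for methylation and most alternatives were fixed before the data were examined. The rule for named genes had to be adapted, since it relied on tests that could not be run. Genes named by it were Uhrf1, Foxp3, Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2 and Tet3, the 12 highest and 12 lowest log2 ratios among genes of at least 5 CPM, and up to 4 called members per list by size of the log2 ratio, or its 2 most abundant members where none was called. Regions named were the Foxp3 elements, the promoters of named genes, the 10 largest falls and 5 largest rises among promoters of called genes, and the 5 DMRs per direction with the largest score. Alternatives covered scaling, filters, the size rule, coverage, the promoter window, the difference called, site weighting, and the treatment of unlisted cytosines.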

Results

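The series holds 8 samples of activated mouse CD4+ T cells, 3 WT and 3 Uhrf1 KO samples for RNA-seq and 1 of each genotype for WGBS. UHRF1 binds hemimethylated CG sites behind the replication fork and recruits the maintenance methyltransferase DNMT1. The series title ties UHRF1 to TGF-β signalling, methylation of Foxp3 and the induction of regulatory T (Treg) cells, and Foxp3 encodes the transcription factor that defines Treg cells. RNA values came from 1 column per genotype, with 39915998 counts in the column labelled WT and 46816353 in the column labelled KO. The WGBS lists held 31503872 CG cytosines in WT and 20493890 in KO, at a median coverage of 9 reads in both. No replicate values were available, whether or not a column merges several samples, so all comparisons are between 2 columns or lists.

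The first question was whether the RNA libraries carried the transcript changes of the deletion. Uhrf1 itself (ENSMUSG00000001228, chromosome 17, 56303321 to 56323486) was at nearly equal levels, with 1760 counts or 43.9 CPM in the WT-labelled library and 1996 counts or 42.8 CPM in the KO-labelled one. The ratio was 0.975 (95% interval 0.914 to 1.04), so the gene-level count did not mark the KO library, and a count per gene cannot show the loss of single exons. Uhrf1 also belongs to the S phase and replication list, whose 46 members had a median log2 ratio of 1.14. Its own log2 ratio of −0.04 was the lowest of that list, level with Rpa1. Whether the deletion sets it apart from these genes was not tested. In the authors' deposited table the log2 fold change of Uhrf1 was −0.04, with an adjusted p of 1.00. Because the target did not separate the libraries, each direction below is given for the library labelled KO. Foxp3 (ENSMUSG00000039521, chromosome X, 7579676 to 7595243) was 23.8-fold higher there (22.2 to 25.6), at 476.6 CPM against 19.99 CPM. The labels name no TGF-β in these cultures.

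Among the genes of DNA methylation, Dnmt1 was 2.22-fold higher in the KO-labelled library (2.16 to 2.28). The ratios of the de novo methyltransferases Dnmt3a and Dnmt3b were 1.26 (1.22 to 1.30) and 0.706 (0.626 to 0.795). Tet1, an enzyme that oxidises methylated cytosine, was 4.97-fold lower (4.36 to 5.66), whereas Tet2 and Tet3 had ratios of 1.37 (1.31 to 1.42) and 0.744 (0.725 to 0.763). Of 29 expressed members of the methylation machinery list, 4 were called higher, 1 lower and 24 neither. The list median log2 ratio of 0.25 lay at the 99.2 percentile of matched lists. Lig1, which joins Okazaki fragments, was 3.24-fold higher (3.04 to 3.45), and Gadd45g, a stress-induced growth arrest gene, 2.66-fold higher (2.44 to 2.91).

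Across 17540 expressed annotated genes, 1284 were called higher in the KO-labelled library and 456 lower, so 73.8% of the called genes were higher. At 8-fold or more the split was 329 higher to 19 lower. The median log2 ratio of all expressed genes was 0.02. With under 3 counts in the WT-labelled library there were 76 genes called higher, and 0 genes called lower had under 3 counts in the KO-labelled one. Cyp11a1, the first enzyme of steroid hormone synthesis, had 1 count against 8743, a ratio of 7513 (1348 to 296800). Ndufa4l2, a mitochondrial gene induced in hypoxia, had 2 counts against 10471, a ratio of 4499 (1245 to 37160). Tnfrsf8, which encodes the activation receptor CD30, had 1 against 5962 counts, and Xist, the noncoding RNA of X inactivation, 2 against 5380. The potassium channel gene Kcnh1 went from 0 to 5347 counts, at least 1532-fold higher. Tuba3b, Slfn4, Azin2, the serpin gene Serpinb1c, Cep112, the collagen gene Col6a5 and Sectm1a completed the 12 highest, with log2 ratios from 9.83 to 8.70.

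The lowest ratio was that of Klrd1, which encodes the lectin receptor CD94 and was 233-fold lower in the KO-labelled library (79.4 to 1134), at 601 counts against 3. Dmbt1 was 93.1-fold lower (31.5 to 454.6) and Nmnat2, an enzyme of NAD synthesis, 24.3-fold lower (15.9 to 39.2). H2-Ob, which encodes a chain of the antigen-loading modulator H2-O, was 13.9-fold lower (12.3 to 15.8), and the long noncoding RNA Mirt1 10.3-fold lower (9.41 to 11.4). Lypd6b, Zscan10, St3gal6, Adam6b, Btc, Myo1f and Arhgap29 made up the remainder, with log2 ratios from −4.09 to −3.19.

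Treg genes were higher as a group in the KO-labelled library. Of 31 expressed members of the Treg signature, 24 were called higher, 0 lower and 7 neither, with a median log2 ratio of 2.55, above all 10000 matched lists. Il10, the gene of a suppressive cytokine, had 0 against 359 counts and was at least 102.8-fold higher. Penk, the enkephalin precursor, and Il1r2, a decoy receptor for interleukin-1, were at least 121.7-fold and 114.0-fold higher. Gzmb, the protease granzyme B, was 80.0-fold higher (68.4 to 94.2). With members shared with other T cell lists left out, 13 of the remaining 19 were called higher and 0 lower, at a median of 2.25.

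Among lists of other helper T cell types, the medians of Th1, Th2 and Th17 genes lay above those of matched lists and that of Tfh genes did not. Th2 genes had 7 called higher, 0 lower and 6 neither of 13, at a median log2 ratio of 3.44. Among them were the cytokine gene Il13 (0 against 990 counts, at least 283.6-fold), the interleukin-33 receptor Il1rl1 (31.8-fold, 19.99 to 54.1) and the transcription factor Maf (29.1-fold, 21.2 to 40.9). Nfil3, another transcription factor of the list, was 16.4-fold higher (14.6 to 18.6). Of 16 Th1 genes, 7 were called higher, 4 lower and 5 neither, at a median of 1.41. The chemokine gene Ccl5 was 36.6-fold higher (18.4 to 85.5) and the transcription factor Eomes 13.4-fold (9.10 to 20.6). Of 10 Th17 genes, 3 were called higher, 0 lower and 7 neither, with a median of 2.62, and Tmem176a, Tmem176b and Stat3 were the called ones. Of the 7, Il1r1, Ccr6, Il21, Ltb4r1 and Ahr had log2 ratios from 5.13 to 1.35 but under 5 CPM. Il17f and Rora had log2 ratios of 0.24 and 0.035. Tfh genes split, with 1 called higher (Pdcd1, 5.85-fold), 3 lower and 11 neither of 15. The lower ones were Pou2af1, Btla and Asap1, and the list median of 0.12 lay at the 72.9 percentile of matched lists. The Th1 median lay at the 99.99 percentile, and those of Th2 and Th17 above all 10000 matched lists.

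The lists of activation and of inhibitory receptor genes had higher medians, and that of naive cell genes a lower one. Of 29 activation and co-stimulation genes, 14 were called higher, 2 lower and 13 neither, at a median log2 ratio of 1.12. The co-stimulatory receptor genes Tnfrsf9 and Tnfrsf4 were 76.2-fold (63.4 to 92.4) and 8.78-fold (8.30 to 9.28) higher. Il2ra, the high-affinity interleukin-2 receptor chain, was 5.86-fold higher (5.76 to 5.97). Tnfrsf9, Tnfrsf4 and Il2ra are also members of the Treg signature. Among the 13, Cd69, Cd28 and Cd44 had log2 ratios of 0.33, 0.03 and −0.35. The 2 lower ones were Rel and Cd40lg, at −1.04 and −1.56. Of 16 inhibitory receptor and exhaustion genes, 8 were called higher, 1 lower and 7 neither, at a median of 1.45. Pdcd1lg2, a ligand of PD-1, was 51.6-fold higher (21.9 to 160.0) and the inhibitory receptor Tigit 28.5-fold (15.3 to 60.1). Tigit is a member of the Treg signature as well, and shared members were not left out of these lists. Of 23 genes of the naive and quiescent state, 0 were called higher, 5 lower and 18 neither, with a median of −0.82, below all 10000 matched lists. Il7r, the interleukin-7 receptor chain that keeps naive cells alive, was 3.77-fold lower (3.62 to 3.92), and Tcf7, a transcription factor of naive cells, 2.72-fold lower (2.68 to 2.76). Ly6c1 and Gimap6 were 4.07-fold and 2.62-fold lower.

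Cell cycle genes were higher in the KO-labelled library. Of 46 S phase and replication genes, 22 were called higher, 0 lower and 24 neither, at a median log2 ratio of 1.14, and of 42 G2 and mitosis genes 35 were called higher, 1 lower and 6 neither, at 1.36. The replication licensing gene Cdc6 was 4.50-fold higher (4.003 to 5.08), the mitotic kinase gene Plk1 3.87-fold (3.60 to 4.17) and Aurka 3.64-fold (3.37 to 3.94). Of 37 p53 targets, 8 were called higher, 1 lower and 28 neither, at 0.70. Cdkn1a, the cell cycle inhibitor p21, was 20.2-fold higher (18.3 to 22.4) and Sesn2 4.85-fold (4.38 to 5.37). Of 22 glycolysis genes, 4 were called higher, 0 lower and 18 neither, at 0.75, with the lactate transporter gene Slc16a3 at 3.37-fold (3.28 to 3.48) and Hk1 at 2.26-fold (2.20 to 2.32). The medians of these 4 lists lay above all 10000 matched lists. Of 28 apoptosis regulators, 3 were called higher (Pmaip1, Bcl2l1 and Bax), 0 lower and 25 neither, and the median of 0.22 lay at the 96.5 percentile.

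Interferon-stimulated genes were higher in the KO-labelled library. Of 62 expressed, 44 were called higher, 0 lower and 18 neither, at a median log2 ratio of 1.59, above all 10000 matched lists. Ifi44 was 45.7-fold higher (30.8 to 70.9), the antiviral GTPase gene Mx1 19.3-fold (15.9 to 23.6) and the RNA-sensing synthetase gene Oas2 14.6-fold (13.5 to 15.9). Among 24 genes of KRAB repression and repeat sensing, 3 were called higher, 0 lower and 21 neither, with the median of 0.15 at the 92.6 percentile. The 3 were nucleic acid sensors, Ifih1 at 4.45-fold (4.15 to 4.78), Aim2 at 2.88-fold (2.68 to 3.10) and Zbp1 at 2.23-fold (2.15 to 2.32). Of 47 germline genes with detectable counts, from 92 found in the table, 14 were called higher, 1 lower and 32 neither. Their median of 2.99 lay above all 10000 matched lists. The meiotic genes Syce1 (0 against 479 counts, at least 137.2-fold) and Tex15 (84.6-fold, 36.0 to 261.6) and the X-linked Xlr3c (2 against 869 counts) were among them. Of 36 imprinted genes, 2 were called higher, 1 lower and 33 neither, and the median of 0.10 lay at the 63.2 percentile. Grb10, a growth factor receptor adaptor, had 3 against 268 counts, a ratio of 76.8 (26.0 to 374.6), next to Ddc at 3.43-fold (2.81 to 4.22), and Peg13 was 2.44-fold lower (2.19 to 2.74). Of 33 TGF-β signalling genes, 6 were called higher, 0 lower and 27 neither, with the median of 0.34 at the 99.5 percentile. They included the integrin gene Itgae (15.9-fold, 12.5 to 20.6) and Lrrc32 (7.06-fold, 6.73 to 7.41), whose product holds latent TGF-β on Treg cells.

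Of the lists for other cell types, B cell and myeloid markers had medians above the range of matched lists, and the remaining 4 lay within it. Of 14 expressed B cell markers out of 21, 1 was called higher (Cd79a, 4.92-fold, 3.997 to 6.09), 3 lower and 10 neither, with the median log2 ratio of 1.37 at the 98.5 percentile. The immunoglobulin genes Ighm and Ighd, the latter counted at 356 against 184, were 2.01-fold and 2.25-fold lower. Of 20 myeloid and dendritic markers, 5 were called higher, 1 lower and 14 neither, with the median of 1.014 at the 99.5 percentile. Cd74, the invariant chain of MHC class II, was 37.7-fold higher (29.2 to 49.6) and reached 56.5 CPM, Adgre1 was 27.5-fold higher (17.2 to 46.7), H2-Eb1, H2-Ab1 and Cebpb had log2 ratios of 2.89, 2.04 and 1.54, and the chemokine receptor gene Ccr2 was 5.85-fold lower (5.33 to 6.43). Of 11 CD8 T cell markers, 2 were called higher, 2 lower and 7 neither (median 0.68, 94.7 percentile), with Eomes and Gzma higher and Klrd1 and Cd7 lower. Of 7 natural killer and innate lymphoid markers, 2 were called higher, 1 lower and 4 neither (median 0.49, 78.1 percentile). Of 9 gamma-delta and NKT cell markers, 1 was called higher and 8 neither (0.25, 66.2 percentile), and of 7 red cell, platelet and stromal markers 1 was called higher, the collagen gene Col1a1, and 6 neither (−0.45, 8.70 percentile). Outside the gene lists, the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had ratios of 0.563, 0.781, 0.502 and 0.778. X-linked genes other than Xist had a median log2 ratio of 0.02 over 551 genes.

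**Figure D1:**
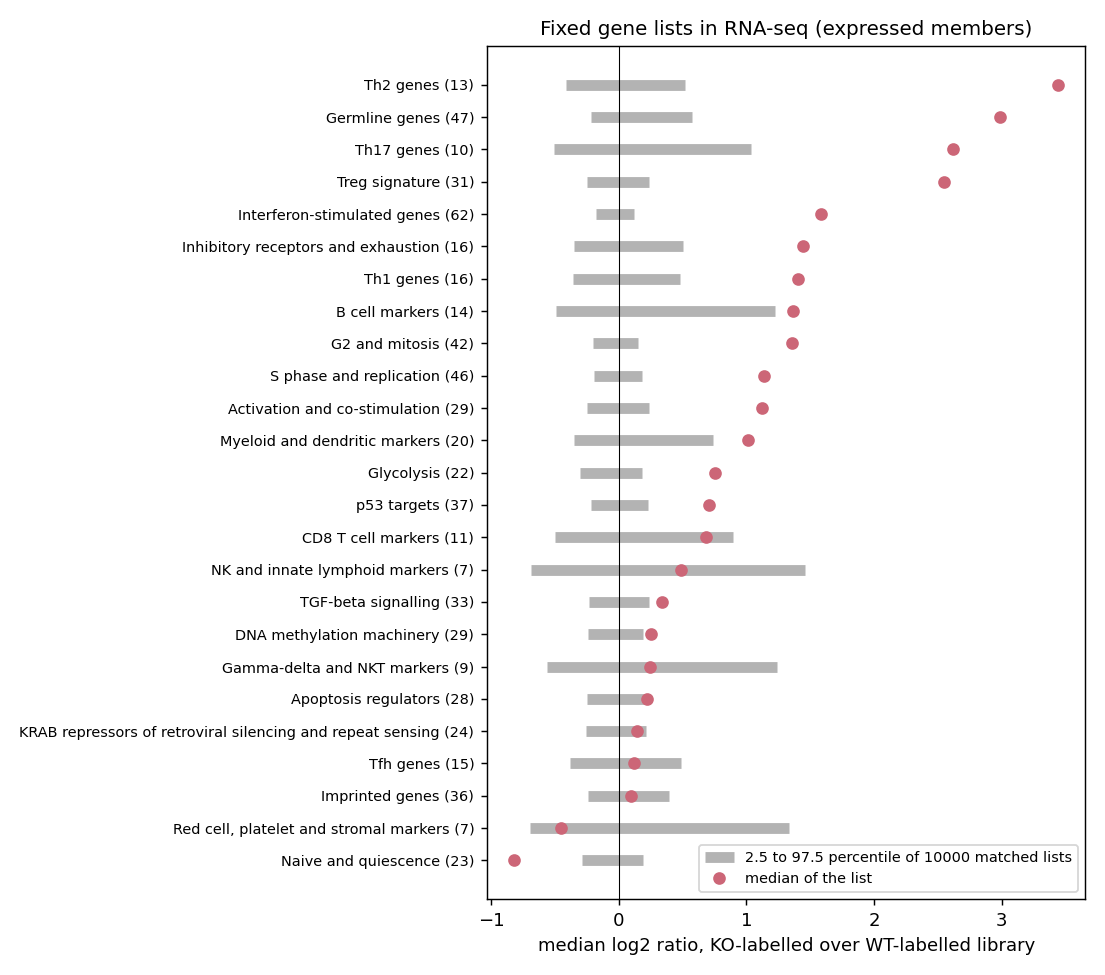
Median log2 ratio of the expressed members of each of the 25 gene lists, KO-labelled over WT-labelled library (x axis), with the number of expressed members after each name; points are list medians and grey bars the central 95% of 10000 lists matched on mean CPM. Th2 genes had the highest median at 3.44, and naive and quiescence genes the lowest at −0.82.

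The RNA counts rest on the size rule and not on a test between genotypes, and a difference in activation, culture, animals or the share of other cell types would enter these lists too, including those of Treg, helper and activated cells. The authors' deposited table, which compared 20494 genes and loci, called 640 up and 186 down. All 594 annotated genes called up in the authors' deposited table were also called higher here, and all 184 called down were called lower, but both calls use the same counts, so this overlap adds no evidence. For Foxp3, the authors' deposited table gave a log2 fold change of 4.57 with an adjusted p of 4.72e-105, and for Il2ra 2.55 with 4.82e-286.

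The WGBS comparison asked how much CG methylation was left without UHRF1. Over the listed CG cytosines of the main chromosomes, the level was 88.6% in WT and 38.4% in KO. With WT-listed cytosines missing from the KO list taken as 0%, the KO mean was 23.4%, and 59.2% of the WT-listed cytosines were listed in KO. At cytosines listed in both libraries the levels were 91.4% and 38.1%. In WT 82.3% of listed cytosines had a level of at least 80%, against 4.32% in KO, and 70.6% of those in KO were under 50%. Autosomes differed little. KO levels ran from 36.7% on chromosome 11 to 39.8% on chromosome 2, and WT levels from 86.3% on chromosome 17 to 89.5% on chromosome 10. On chromosome X, at a median coverage of 6 reads in each library, the listed level was 89.5% in WT and 44.8% in KO, with 23.3% of the WT-listed cytosines listed in KO. The other measures put X below the autosomes in KO, so the listed level does not show more methylation left on X. With missing cytosines taken as 0% the KO mean of X was 10.6%, against 22.1% to 25.4% on autosomes, although low coverage also lowers this figure. In the authors' deposited table, CG regions had a median KO mean of 22.4% on X and 27.3% on autosomes.

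Methylation outside CG was sparse in both lists. CHG cytosines numbered 485778 in WT and 314793 in KO, and with at least 3 methylated reads 44511 and 23499. For CHH the lists held 160293 in WT and 852662 in KO, but their minimum differed, and with at least 3 methylated reads the KO list held 93119. The listing rule sets the level over such rare cytosines, so counts alone are given.

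**Figure D2:**
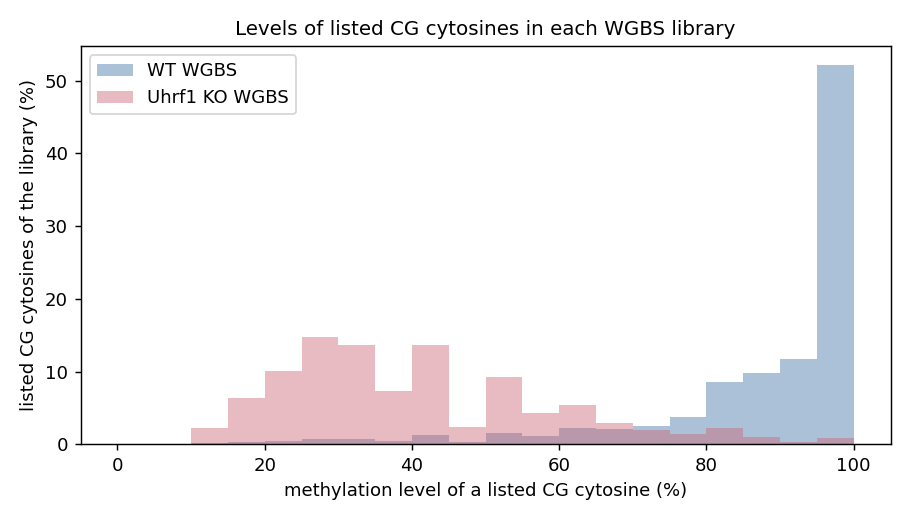
Share of listed CG cytosines of each WGBS library (y axis, percent) by methylation level in steps of 5 points (x axis, percent). WT cytosines gather near full methylation, with 82.3% at a level of at least 80%, and KO cytosines mostly between 10% and 60%, with 4.32% at a level of at least 80%; unlisted cytosines are absent from both.

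Promoters, gene bodies and intergenic sequence all had lower methylation in KO. Listed promoter cytosines were at 81.5% in WT and 41.9% in KO, a difference of −39.6 points (−39.7 to −39.6). Gene bodies outside promoters were at 89.6% and 37.9%, a difference of −51.7 points, and intergenic cytosines at 88.2% and 38.6%, a difference of −49.6 points. Of 36676 promoters with at least 5 listed CG cytosines in each library, 34334 (93.6%) were lower in KO by at least 20 points, 3 were higher and 2339 were neither. The median promoter stood at 88.0% in WT and 35.7% in KO, with a median difference of −48.3 points. Medians of 23 listed cytosines and 233.0 reads in WT, and of 14 and 140.0 in KO, stood behind these levels. Unmethylated cytosines of a promoter are unlisted in WT as well as in KO. The levels therefore describe listed cytosines alone, and an unmethylated part of the window does not lower them. A promoter with its cytosines unlisted in either library did not enter this count.

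Among genes called in RNA, the promoters with the largest differences belonged to Dnase1, Asah2, Prok1, Cdca8, Pparg, Mzf1, Car9, Asb14, Stat4 and Rpgrip1. Dnase1, an extracellular nuclease gene, had a promoter window (chromosome 16, 4035942 to 4037442) at 92.9% in WT (89.4 to 95.3) and 21.4% in KO (14.6 to 30.2). Pparg, a nuclear receptor of lipid metabolism, was at 93.4% (89.1 to 96.1) and 23.3% (16.2 to 32.3), and its log2 ratio in RNA was 6.93. Car9, a carbonic anhydrase gene, was at 98.1% (96.2 to 99.1) and 30.5% (24.2 to 37.6), with a log2 ratio of 5.91. Stat4, a Th1 transcription factor, was at 90.4% (87.1 to 92.9) and 23.4% (17.5 to 30.6), with a log2 ratio of −1.19. In the other direction stood Stk11ip, Ppil1, Gmnn, AB124611 and S100a1. Stk11ip was at 39.0% in WT and 75.4% in KO over 8 and 7 cytosines. That difference of 36.4 points reversed to −39.7 with the window from 2000 bp upstream to the gene start, and to −15.5 with missing cytosines taken as 0%. The differences of the other 4 were 10.3 points or less, and they turned as well. With missing cytosines taken as 0% they were −20.5 for Ppil1, −27.2 for Gmnn, −15.6 for AB124611 and −29.5 for S100a1, so none of the 5 is a settled rise.

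Of 110 named genes, 87 had a measured promoter, and 72 of these were lower by at least 20 points. The same rule was met by 93.6% of all 36676 measured promoters, so it does not single out the named genes. The Xist promoter (chromosome X, 103482717 to 103484217) was at 93.3% in WT (90.6 to 95.3) over 56 listed cytosines and 49.7% in KO (42.1 to 57.3) over 22. The Il13 promoter was at 86.3% and 35.5%, that of Gzmb at 80.7% and 32.8%, and that of Cdkn1a at 87.6% and 24.5%. Among germline genes, the Tex15 promoter was at 89.6% in WT and 62.1% in KO, Tuba3b at 97.495% and 63.8%, and Syce1 at 88.9% and 41.3%. Promoters of genes with lower transcript ratios also had lower levels, with 91.3% and 28.5% for Tet1, and 71.1% and 25.9% for Il7r. Klrd1 was among 23 named genes with too few listed cytosines, as were Foxp3, Penk, Maf and Nfil3. The Uhrf1 promoter itself was at 73.6% in WT and 31.4% in KO, over 14 and 16 listed cytosines. With missing cytosines taken as 0%, the KO means were 14.8% for Xist, 17.5% for Il13, 29.1% for Gzmb and 15.0% for Cdkn1a. For the germline genes Tex15, Tuba3b and Syce1 they were 46.1%, 57.6% and 19.5%.

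At the Foxp3 locus, all 3 elements with listed sites had a lower level in KO over both strands together. CNS2 (chromosome X, 7583938 to 7584463), the intronic enhancer whose demethylation marks stable Treg cells, was at 99.4% in WT (96.6 to 99.9; 164 reads, 20 cytosines) and 72.7% in KO (58.2 to 83.7; 44 reads, 8 cytosines). The Fisher's exact test between the 2 libraries gave an adjusted p of 7.05e-08. Reads at each element were summed over its cytosines, so a fragment that crosses several of them is counted several times. The tests at all 3 elements take these counts as independent, so their p-values may be too small. The promoter window (7578676 to 7580176) was at 76.0% over 14 cytosines and 50.0% over 4, and CNS1 (7581679 to 7582381) at 87.5% over 4 and 51.4% over 5, each with an adjusted p of 0.00786. These differences depended on the strand. CNS2 differed by −54.5 points on the plus strand and −16.3 on the minus strand. CNS1 went from 83.3% over 3 cytosines to 5 methylated of 5 reads at 1 cytosine on the plus strand, and from 6 of 6 reads at 1 cytosine to 43.75% over 4 on the minus strand. The promoter had listed KO cytosines on the plus strand alone, where it differed by −37.1 points. Only 4 promoter, 2 CNS1 and 5 CNS2 cytosines were listed in both libraries, so the tests compare largely different cytosines, and the direction at CNS1 is not settled by these sites. CNS3 (7586585 to 7586779) had 0 listed CG cytosines in either library. Over the gene span the levels were 95.9% (94.6 to 96.9) in WT and 48.3% (44.6 to 52.1) in KO. With missing cytosines taken as 0%, the KO means were 14.2% for the promoter, 30% for CNS1 and 17.3% for CNS2. Across chromosome X, at a median coverage of 6 reads, 23.3% of WT-listed cytosines were listed in KO. Many missing cytosines may therefore lack reads, which lowers these means. The authors' deposited table lists 17 CG regions across the locus, all lower in KO, with other bounds than the elements. In the authors' deposited table, the intronic region 7583423 to 7584136, which overlaps CNS2, was at 96.9% in WT and 57.3% in KO, the highest KO mean of the 17. The region 7580008 to 7581349 begins downstream of the gene start and overlaps the end of the promoter window. It had 96.4% in WT and 27.6% in KO, and the intronic region 7581943 to 7582109 in CNS1 had 95.2% and 38.5%, per the authors' deposited table.

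**Figure D3:**
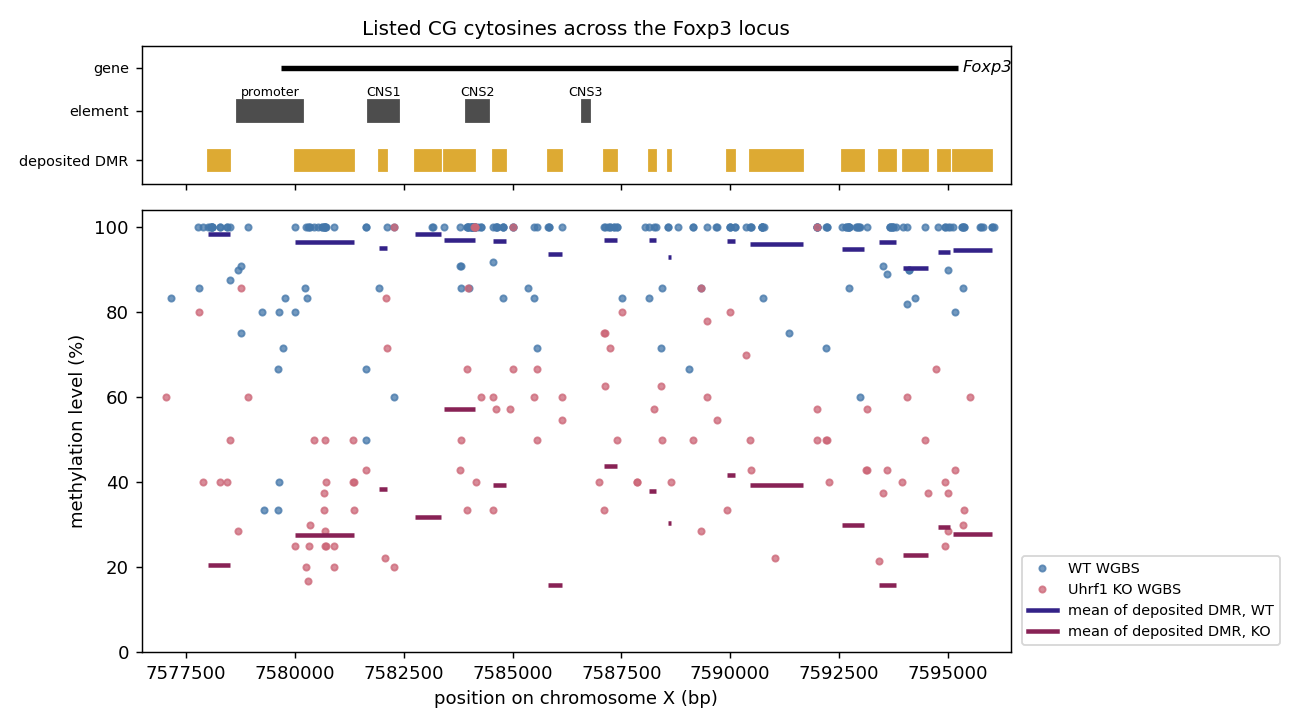
Map of the Foxp3 locus on chromosome X (x axis, bp) with the gene, the 4 elements and the authors' deposited DMRs (upper panel), and the methylation level of each listed CG cytosine in percent (lower panel; points are cytosines, bars the deposited means per region). WT bars lie above 90% across the locus, while KO bars lie between 15.9% and 57.3%, highest at CNS2.

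The DMR calls of the authors showed how one-sided the difference was. The authors' deposited table lists 831667 CG regions lower in KO and 22 higher, the former covering 1394.8 Mb at median means of 91.3% in WT and 27.1% in KO. Of the lower CG regions in the authors' deposited table, 63.1% overlapped a gene body and 6.73% a promoter window by at least 1 bp. The region with the largest score in the authors' deposited table covered most of Dnmt1 (chromosome 9, 20907603 to 20945413), with 1365 cytosines at 95.4% in WT and 24.8% in KO. It was followed in the authors' deposited table by regions at Cog2 and Agt (chromosome 8), Polr1c and Xpo5 (chromosome 17), the histone methyltransferase gene Kmt2a (chromosome 9) and the dynein gene Dync1h1 (chromosome 12), with KO means from 21.9% to 28.6%. Outside CG, the authors' deposited table has 770 CHG regions lower and 144 higher, and 14150 CHH regions lower and 4366 higher. The 5 largest scores for a higher level in KO were CHH regions in the authors' deposited table. They lay in introns of Homer2 (chromosome 7, 81649774 to 81650136; 0.758% in WT, 30.01% in KO), Tlk2 and Gm29502, and near Grid1 and Gm15766, per the authors' deposited table.

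The last comparison set promoter methylation beside RNA. Among 5069 genes of at least 5 CPM whose promoter was at 50% or more in WT and lower by at least 20 points, 13.02% (12.1 to 14.0) were called higher in the KO-labelled library and 4.60% (4.05 to 5.21) lower. Lists of genes matched on CPM gave a median of 12.8% higher, with a range of 11.9% to 13.7%. Of the other 1001 genes with a measured promoter, 13.7% (11.7 to 15.95) were higher and 4.50% (3.38 to 5.96) lower. Both groups need 5 listed cytosines in KO, and a promoter that lost its methylation entirely is left out. Unmethylated cytosines are unlisted in WT too, so a promoter methylated at only part of its cytosines can meet the rule. The rule took in 5069 of the 6070 measured genes and cannot separate methylated from largely unmethylated promoters. Similar shares in the 2 groups therefore do not decide whether loss of promoter methylation altered RNA. A further 2224 genes had 5 or more listed promoter cytosines in WT and under 5 in KO, through low levels or low coverage, and 12.9% (11.5 to 14.3) of these were higher and 4.18% (3.43 to 5.10) lower. With missing cytosines taken as 0%, 6701 genes met the rule for demethylated promoters, and 12.8% (12.04 to 13.6) of them were higher and 4.49% (4.02 to 5.01) lower. Genes with under 5 listed promoter cytosines in WT, 2405 in number, were higher in 8.32% (7.28 to 9.49). Across 6070 genes, which are not independent replicates, Spearman's rho between promoter difference and log2 ratio was 0.0071. The promoter difference itself followed the listed WT level, at a rho of −0.77 across the same genes. The Cyp11a1 promoter, for example, was at 49.8% in WT and 36.6% in KO, and that of Serpinb1c at 89.5% and 33.3%. With missing cytosines taken as 0%, the KO means of these 2 promoters were 20.2% and 19.6%. The RNA and WGBS cells differed in culture time and mouse age, and genes were joined across assays by position in 1 library each.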

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

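The test of Y-linked genes and the version without unmeasured promoters of the last swap test were chosen after their values were seen, and the test on genes silent in the WT-labelled library was added once the first test for swapped columns had turned out to decide nothing; all bear on the patterns weighed here.

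Transcripts from loci without annotation stood outside the gene comparisons and were higher in the KO-labelled library. Of 180 such loci with at least 5 CPM, 96 were at least 2-fold higher there and 21 lower. The locus with the highest ratio, on chromosome 1 from 192163815 to 192184090, had 14634 counts in the KO-labelled library and 0 in the WT-labelled one, at least 4192-fold higher. It ends shortly upstream of Kcnh1 and is listed on the same strand.

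The Uhrf1 transcript was not lower in the KO-labelled library, with a ratio of 0.975, although the S phase and replication list that holds it had a median log2 ratio of 1.14. A swap of the 2 RNA columns was tested first on genes with demethylated promoters. Of those 2-fold apart, 73.9% (70.9 to 76.7) were higher in the KO-labelled library, but all expressed genes gave 73.8% (71.7 to 75.8), so the bound set for that test was wrong and it decides nothing. Of 76 genes with under 3 counts in the WT-labelled library, 63 (82.9%) had a WT promoter at 50% or more, at the 99.965 percentile of matched lists, whose median was 64.5%. However, 4 of the 76 and 2356 of 10271 comparison genes had under 5 listed cytosines in WT and were counted as not methylated. Without such genes the share was 63 of 72 (87.5%), at the 94.135 percentile of matched lists, whose median was 80.6%. The added test therefore depends on how unmeasured promoters are counted, and a swap is not excluded. Reads from exons left by the deletion cannot be told apart from an intact transcript by a count per gene, so they remain a candidate explanation, as does a deletion in only part of the cells.

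Xist had 2 counts in the WT-labelled library and 5380 in the KO-labelled one. If Xist RNA silenced X-linked genes of cells with a single X, these would lie low, but their median was at the 40.975 percentile of matched lists, which argues against silencing across the chromosome. Cells of female mice could account for Xist, and the Y-linked genes had a median ratio of 0.670. However, their ratios ran from 0.502 (0.484 to 0.521) for Ddx3y to 0.781 (0.727 to 0.839) for Uty, further apart than 1 share of male cells would put them, so Y-linked values neither exclude nor single out a mixture of sexes. Lower methylation of the Xist promoter in the KO WGBS library stays open as a biological explanation and was not tested in the RNA cells.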

How the results depend on the processing

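No paired analysis was possible because the count table has 1 column per genotype and carries no replicate numbers. Also not run for lack of replicates were DESeq2, limma voom, the filter of 10 counts in 3 samples, leaving out samples, the use of numbered samples alone, camera and fry, and DESeq2 calls beside promoters. The planned size limit of log2 1 was already in use, a coverage minimum of 1 lies under the lists' own minimum, and the DMR table has no p-value to tighten. Chosen after seeing the data were the CPM minimums, the fold of 4, the coverage minimum of 20, missing cytosines taken as 0%, the strand with fewer reads, and the DMR limits of 30 points and 10 cytosines.

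Under 3 other scalings, 405 log2 ratios and list medians, Uhrf1 and Foxp3 included, shifted by at most 0.012 and 0 changed sign. The RNA counts followed the size rule by construction. Without a CPM minimum 3393 genes were higher and 1497 lower, at 1 CPM 2210 and 860, and at 4-fold 535 and 64. Of 97 further values, 49 stayed within their interval or 1.5 times the count; the cause of the other shifts was not tested beyond what each setting removes or adds.

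Every difference between KO and WT over genome, features and Foxp3 elements kept its sign, except at CNS1 on 1 strand. The CG level in WT and KO was 88.3% and 35.3% at coverage 10, 84.9% and 40.0% at coverage 20, 88.9% and 40.0% as means of sites, 91.4% and 38.1% at sites in both lists, and 88.6% and 38.3% on autosomes. With missing cytosines as 0% the KO level was 23.4%. The differences for promoters, gene bodies and intergenic cytosines were −39.7, −54.3 and −53.1 points at coverage 10, and −35.1, −47.9 and −53.9 at coverage 20. They were −41.6, −50.4 and −47.7 as means of sites, −43.5, −54.5 and −52.9 at sites in both lists, and −59.5, −65.9 and −65.5 with missing as 0%.

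Promoters lower in KO numbered 22604 at coverage 10 and 141 at coverage 20, where fewer had enough sites. The 3 higher promoters became 0 at coverage 20, at sites in both lists and with missing as 0%, and 1 at a difference of 30 points. With missing as 0% the Foxp3 promoter, CNS1 and CNS2 differed by −58.9, −56.4 and −82.0 points. On the strand with more reads, CNS1 differed by −56.3 and CNS2 by −54.5 points, and the promoter had no KO value. On the strand with fewer reads, CNS1 reversed to 16.7 points, from 18 reads in WT and 5 in KO, while CNS2 differed by −16.3 and the promoter by −37.1. The share of genes with a demethylated promoter that were lower in RNA became 6.25% at coverage 20. Stk11ip reversed to −39.7 points with the window from 2000 bp upstream and to −15.5 with missing as 0%. The smaller rises turned too, with −12.7 and −20.5 for Ppil1, −24.7 and −27.2 for Gmnn, −23.6 and −15.6 for AB124611, and −58.8 and −29.5 for S100a1. Of 465 alternatives for 102 named promoters, 162 moved past their interval, 149 to a lower and 13 to a higher difference. In the authors' deposited table, 7 CG regions higher in KO differed by 30 points, and with an overlap of 50% of the region the shares in promoters and gene bodies were 3.12% and 61.0%. Depth limits chromosomes X and Y, both at a median of 6 reads, and Foxp3 elements on X rest on 4 to 20 listed cytosines per library.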

Other observations

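The comparisons of CpG islands, repeat classes and higher regions were chosen after the tables were first looked at; the tests on ERVK regions and on unannotated loci were set before their results were seen.

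Among the called CG regions, of which 22 were higher in KO and all others lower, those that touch a CpG island had the higher KO levels. In the authors' deposited table, 8495 CG regions of either direction touched a CpG island, with median means of 93.8% in WT and 48.3% in KO. Regions with exons, introns and 5′ UTRs had KO medians of 27.2%, 27.8% and 26.0% in the authors' deposited table. Islands outside these calls were not measured, and the regions were not matched on cytosine density, length or WT level. The 22 CG regions higher in KO were short, with a median of 115.5 bp, and 7 of them differed by at least 30 points in the authors' deposited table. By score the first 5 lay at Fam171a2, Igf2r with Airn, Mpp7, Shank3 and Tbc1d10b. The region at Igf2r and Airn (chromosome 17, 12769410 to 12769622) was at 35.6% in WT and 68.8% in KO in the authors' deposited table. A region in the imprinted gene Sgce (chromosome 6, 4746870 to 4746963) was at 19.16% and 51.3% there, per the authors' deposited table.

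Regions annotated with an LTR of the ERVK class of endogenous retroviruses had a median KO mean of 32.6% in the authors' deposited table, against 25.5% for LINE L1 regions. The repeat names of this annotation include element families of primates, so which mouse elements these regions hold is not known. Over all other repeat regions the excess was 6.04 points (95% bootstrap interval 5.67 to 6.39 over blocks of 1 Mb). After matching on cytosine density and region length it was 5.32 points (5.01 to 5.63), and after matching on the WT level as well 3.93 points (3.68 to 4.22). Density, length and starting level therefore do not account for the whole excess. Retention of methylation at ERVK elements by other silencing pathways is a candidate explanation that was not tested, and reads that map to several ERVK copies remain open.

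A hypothesis for the unannotated transcripts was that they start in LTR elements that lost methylation. Of the 96 higher loci, 25% (17.4 to 34.5) had a deposited LTR region within 1 kb of their start, against 14.3% (8.37 to 23.3) of the other 84. The intervals overlap, so the data leave open whether LTR elements may be a source of these transcripts.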
